A study of Homo sapiens with 4 samples.

How the data were processed

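The series measured poly(A)-selected RNA by paired-end Illumina sequencing in H1, an established human embryonic stem cell line, grown in E8, a defined medium that contains insulin, FGF2 and TGFβ. The labels give 4 samples at 12 h: 2 in E8 alone and 2 in E8 with 1 µM XMD892, a small-molecule inhibitor of the kinase ERK5. A single table of 19775 genes was deposited for the whole series, with 9 columns of per-library values. Column names were matched to the samples' labels by treatment, time and replicate number. Of the columns named for XMD892 at 12 h, 2 matched 1 sample each. A further column carries the same treatment and time with replicate number 3, which none of the samples' labels give, and it was set aside. In all, 7 columns were not used here, since their names matched none of the 4 samples; the untreated columns carry another culture time than the one in the untreated samples' labels. The 2 samples in E8 alone were therefore not analysed here, and the planned test of XMD892 against E8, with its gene set tests, was not run. What follows describes the treated cells and the agreement of the 2 treated libraries, and contains no effect of the compound. The labels do not say whether the 2 libraries came from separate cultures, so the spread between them may be technical.

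The values are a normalized signal: gene counts that the authors divided by 1 size factor per library before they deposited the table, which is shown by the values themselves. Every value in both columns was a whole multiple of 1 step per column (100% of 19775 values within 0.01 reads), so whole reads were recovered by dividing by that step. The size factors obtained were 0.932 for replicate 1 and 0.948 for replicate 2. Trimmomatic 0.36, STAR, featureCounts 1.5.3, DESeq2 1.26.0 and the human build hg38 are named, per the submitters' processing notes, without their roles. The gene annotation, the strand setting of the counting and the rule by which genes entered the table are not given in the sources used here. A gene that is missing from the table is reported as not listed, never as 0.

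Recovered reads came to 18528689 in replicate 1 and 20217648 in replicate 2. Levels are given as RPKM (reads scaled by exon length in kilobases and by the library's recovered reads), computed here with the merged exon length of all transcripts in GENCODE release 29 on GRCh38, the assembly that hg38 names. Symbols were matched exactly, and 19283 of the 19775 had 1 gene ID in that release; the other 492 have no RPKM. Merged exon lengths understate the level of genes with long rare isoforms, so differences between genes in RPKM are approximate. Means are given ± SD over the 2 libraries. Intervals on the ratio of the libraries are exact binomial (Clopper-Pearson) 95% intervals on the recovered reads, rescaled by the size factors. They cover counting error only, since the reads carry no molecular identifiers.

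The difference between the libraries is log2(normalized count + 1) in replicate 2 minus that in replicate 1, over the 16148 genes with a mean normalized count of at least 10. This scale understates the difference of low genes. With a single library on each side, and the further column of the same treatment and time not used, these values do not show which of the 2 libraries is the unusual one. There is no replicate check of any such difference and no p-value is given. The biological coefficient of variation was estimated on the recovered reads with edgeR 4.0.16 in R 4.3.3, in a model with an intercept alone. For each gene list, the median difference was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. A list with at least 5 members above the expression minimum was said to stand apart when its median fell outside the central 95% of those random lists. This is a description of these 2 libraries. Genes of 1 pathway vary together more than random genes do, so more lists than the chance share can stand apart without any difference in treatment.

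Before the data were examined, 29 gene lists with 478 different genes were fixed for this cell type, the kinase cascade, the lineages and other cell types a culture could hold, and stress; 417 of the genes were listed in the table. The naming rule fixed then had 4 parts. The kinase and its activator (MAPK7, MAP2K5) and 16 pluripotency, ligand and target genes are given as fixed. The parts that needed the comparison with E8 were replaced after the values were seen. In their place, the text draws on the 12 genes with the largest difference in each direction among those with a mean normalized count of at least 50 and an ordinary symbol. Some items that these rules name are not reported here. From the lists it names mainly the members with the highest RPKM, and others where a count refers to them. The lists of receptors, imprinted genes, second HIF targets, actin and SRF targets and second fibroblast genes, with the ribosomal protein genes and the lincRNAs, were also chosen after the values were seen.

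The steps were tested on simulated data. For the 2 XMD892 libraries, counts for the 16148 tested genes were drawn with a coefficient of variation of 25%, and 200 genes were changed. The estimate returned 26.6%. A gap of at least 2-fold was found for 60% of the genes changed 2-fold, 94% of those changed 4-fold and 98% of those changed 8-fold, and also for 7.89% of the unchanged genes. None of 28 unchanged lists (0%) was placed outside the central 95%, and 67.9% of lists shifted by 0.5 on the log2 scale were placed above it. The simulated genes varied independently of each other. The 0% therefore does not tell how often lists of genes that vary together stand apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the pseudocount, the expression minimum, the scaling between libraries, the transcript length behind RPKM, leaving out each library, and a correction for transcript length and GC content.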

Results

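RNA from H1 human embryonic stem cells that had been kept for 12 h in E8 medium with 1 µM XMD892 was profiled in 2 libraries, called replicate 1 and replicate 2 here. The series asks how ERK5, a mitogen-activated protein kinase encoded by MAPK7, acts on signals that pluripotent cells make for themselves. The 2 libraries in E8 alone were not analysed here, so the values below are levels in treated cells and differences between treated libraries, not effects of the compound. Replicate 1 held 18528689 reads on listed genes and replicate 2 held 20217648. At least 1 read was counted for 19530 and 19561 of the 19775 listed genes. In both libraries 11482 genes reached 1 RPKM, and 10351 of these were protein-coding.

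The most abundant transcript was MT-CO1, a mitochondrially encoded subunit of cytochrome c oxidase, at 9840 ± 823 RPKM (SD, n = 2). The 13 mitochondrially encoded protein genes took 5.08% ± 0.372 of the reads, and the 84 cytoplasmic ribosomal protein genes took 7.53% ± 2.03. EEF1A1, a translation elongation factor, reached 2366 ± 772 RPKM. The cytoskeletal actins ACTG1 and ACTB followed among nuclear genes by normalized count, at 1683 ± 12.1 and 1333 ± 341 RPKM.

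Pluripotency genes were among the more abundant transcripts of the treated cells. All 20 genes of the core pluripotency list were listed and 19 reached 1 RPKM in both libraries. Their median was 62.4 RPKM, against 2.31 RPKM over all genes with a length. POU5F1, which encodes the core factor OCT4, stood at 1082 ± 492 RPKM (SD, n = 2) and at 65305 ± 32583 normalized counts. The gene lies on chromosome 6 at 31164337 to 31180731 on the minus strand (GRCh38), and its reads can be shared with several near-identical pseudogenes. SOX2 stood at 94.5 ± 6.06 RPKM and lies on chromosome 3 at 181711924 to 181714436 on the plus strand. NANOG stood at 29.3 ± 1.07 RPKM, lies on chromosome 12 at 7787794 to 7799141 on the plus strand and also has near-identical pseudogenes. LIN28A, an RNA-binding protein that blocks let-7 maturation, reached 469 ± 95.01 RPKM, and the de novo DNA methyltransferase DNMT3B reached 336 ± 129 RPKM. OTX2, a transcription factor of primed cells and of the anterior neural plate, was the lowest member at 1.31 ± 1.13 RPKM, with 128 reads in replicate 1 and 34 in replicate 2. The genes of naive pluripotency were far lower. Of 14 such genes 9 were listed, 1 reached 1 RPKM in both libraries, and the median was 0.326 RPKM. The highest was TFCP2L1 at 1.41 ± 0.196 RPKM, followed by KLF4 at 0.954 ± 0.0688 RPKM.

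**Figure D1:**
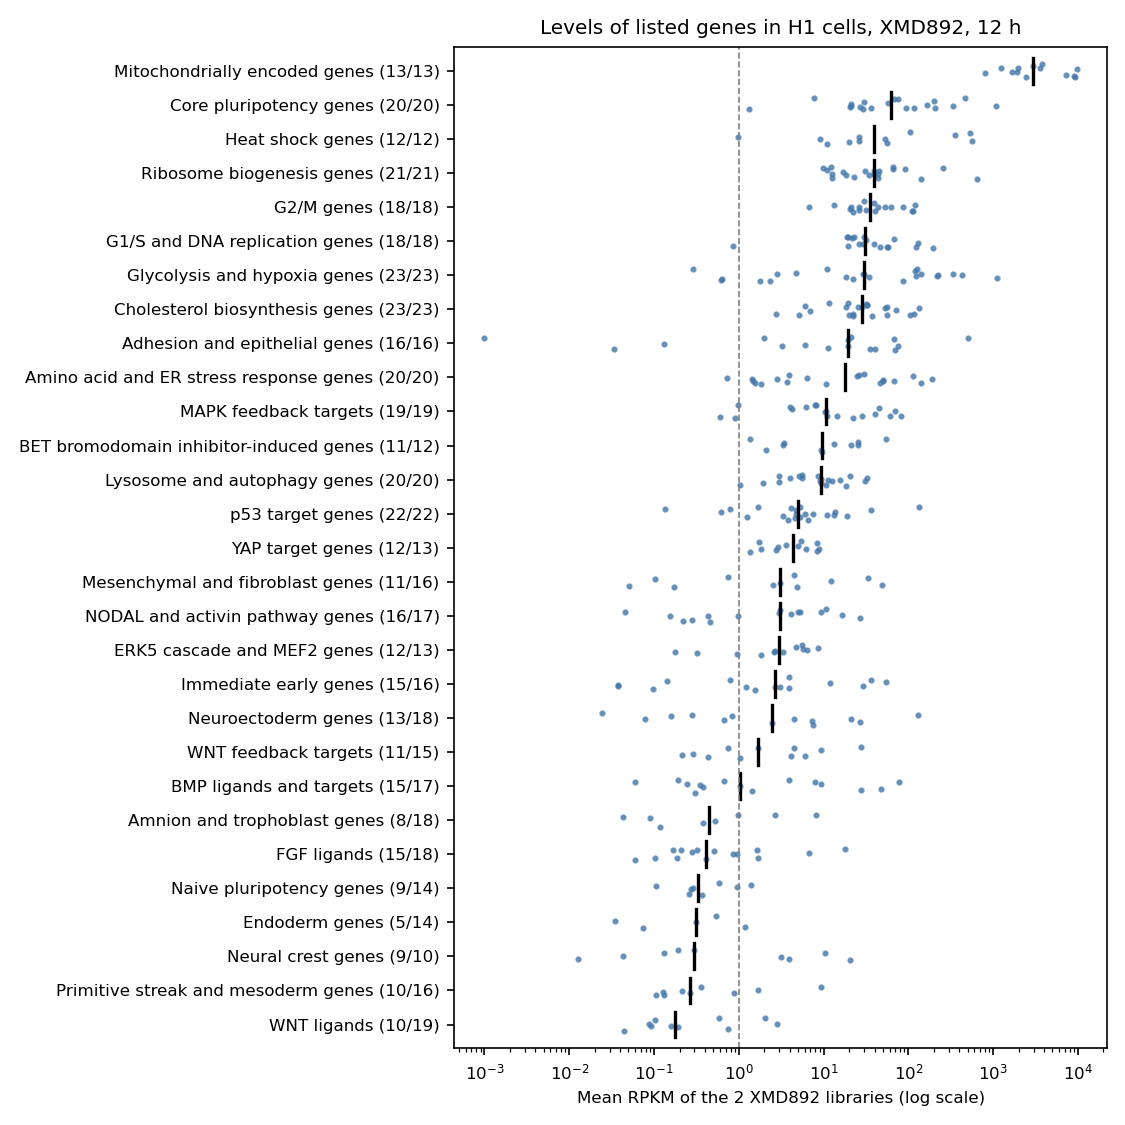
Mean RPKM of the 2 XMD892 libraries (log scale) for the listed genes of each fixed gene list; each point is a gene, the black bar is the list's median, the dashed line is 1 RPKM, and the numbers in brackets are the genes listed in the table out of those in the list. Core pluripotency genes have a median of 62.4 RPKM, while the medians of the naive, endoderm, primitive streak and WNT ligand lists lie under 1 RPKM.

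Transcripts of secreted signals were detected at low to moderate levels. NODAL, a TGFβ family ligand that maintains primed pluripotency, stood at 4.96 ± 1.25 RPKM (SD, n = 2) with 128 and 200 reads. It lies on chromosome 10 at 70432315 to 70447951 on the minus strand. Its relative GDF3 stood at 9.41 ± 4.37 RPKM. The NODAL antagonists LEFTY1 and LEFTY2 stood at 4.12 ± 2.24 and 0.986 ± 0.488 RPKM, and reads can be split wrongly between these neighbouring near-copies. Of the 17 genes of the NODAL and activin list, 16 were listed and 9 reached 1 RPKM in both libraries. FOXH1, the DNA-binding partner of SMAD2 and SMAD3 in NODAL signalling, was the highest at 26.9 ± 3.22 RPKM. TGFB1 stood at 3.10 ± 0.327 RPKM.

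Of the 18 genes of the FGF ligand list, 15 were listed and 4 reached 1 RPKM in both libraries. These were FGF19, FGF2, FGF13 at 1.67 ± 0.220 and FGF12 at 1.65 ± 0.0374 RPKM. FGF11, FGF12 and FGF13 encode intracellular members of the family and not secreted ligands. FGF19 was the highest at 17.8 ± 0.903 RPKM and FGF2, which the medium also supplies as protein, followed at 6.65 ± 1.90 RPKM. FGF2 lies on chromosome 4 at 122826708 to 122898236 on the plus strand. FGF8 stood at 0.846 RPKM in the mean, on 22 and 24 reads, and FGF4 at 0.512 ± 0.228 RPKM, on 21 and 44 reads. Their depth gives little precision: the counting interval of the ratio of the libraries for FGF8 ran from -0.80 to 1.00 on the log2 scale. Among 19 WNT ligands, 10 were listed and 2 reached 1 RPKM in both libraries, WNT5A at 2.85 ± 0.166 and WNT9A at 2.04 ± 0.484 RPKM. WNT3 stood at 0.748 ± 0.0887 RPKM on 55 and 71 reads. BMP4 was at 1.03 ± 0.111 RPKM. The BMP targets ID3 and ID1, inhibitors of helix-loop-helix factors, were higher at 77.3 ± 8.32 and 47.1 ± 8.88 RPKM.

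Within the ERK5 cascade, MAPK7 stood at 5.76 ± 1.06 RPKM (SD, n = 2) and its activating kinase MAP2K5 at 2.59 ± 0.0870 RPKM. MAPK7 lies on chromosome 17 at 19377721 to 19383544 on the plus strand. The compound acts on the kinase protein, so these transcript levels do not measure inhibition. The highest member of the ERK5 list was SQSTM1, an autophagy adaptor, at 8.55 ± 2.36 RPKM. Of the listed MEF2 factors, a family that ERK5 phosphorylates, MEF2A was the highest at 4.79 ± 0.00535 RPKM and MEF2C the lowest at 0.176 ± 0.144 RPKM. KLF2, a known target of the cascade in endothelial cells, stood at 0.323 ± 0.110 RPKM on 15 and 10 reads. Feedback targets of the ERK1 and ERK2 branch were well expressed: 16 of 19 reached 1 RPKM in both libraries, with a median of 10.6 RPKM. CCND1 (cyclin D1) stood at 81.5 ± 25.1 RPKM, the ETS factor ETV4 at 69.7 ± 4.88 RPKM, the phosphatase DUSP6 at 61.4 ± 30.00 RPKM and the receptor signalling inhibitor SPRY4 at 39.9 ± 1.48 RPKM. The immediate early genes were led by JUND at 54.1 ± 12.5 RPKM and MYC at 36.8 ± 11.3 RPKM, with FOS and EGR1 at 3.86 ± 0.303 and 1.21 ± 0.123 RPKM. Among genes known to be induced by BET bromodomain inhibitors, HEXIM1 stood at 21.1 ± 5.51 RPKM, and all 11 listed members of 12 reached 1 RPKM in both libraries.

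Lineage genes were mostly low or not listed. Of 14 endoderm genes 5 were listed and 0 reached 1 RPKM in both libraries, with HHEX the highest at 1.19 ± 0.621 RPKM. Of 16 primitive streak and mesoderm genes 10 were listed and 1 reached 1 RPKM in both libraries, the receptor KDR at 9.23 ± 0.487 RPKM. Of 18 amnion and trophoblast genes 8 were listed and 2 reached that level, TFAP2C at 8.15 ± 0.891 and IGFBP3 at 2.65 ± 1.58 RPKM. TFAP2C is also expressed in pluripotent cells. The neuroectoderm list had 13 of 18 genes listed and 7 at 1 RPKM in both libraries. Its highest members were NES (the intermediate filament nestin) at 129.8 ± 56.7 RPKM, SIX6 at 26.9 ± 4.94 and SOX3 at 20.9 ± 6.25 RPKM. Of 10 neural crest genes 9 were listed, led by FOXD3 at 20.53 ± 0.974 RPKM, a gene that the core pluripotency list also holds. Of 16 mesenchymal and fibroblast genes 11 were listed and 6 reached 1 RPKM in both libraries. THY1, which human pluripotent cells also carry, led at 48.9 ± 21.5 RPKM, and TAGLN (transgelin, an actin-binding protein) followed at 33.8 ± 40.2 RPKM.

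Genes of growth and metabolism were high. All 18 G2/M genes and 17 of 18 G1/S and DNA replication genes reached 1 RPKM in both libraries, with medians of 35.5 and 31.03 RPKM. PCNA, the replication clamp, stood at 196 ± 8.49 RPKM and CCNB1 (cyclin B1) at 121 ± 10.8 RPKM. All 21 ribosome biogenesis genes reached 1 RPKM, led by NPM1 (nucleophosmin) at 639 ± 70.2 RPKM. All 23 cholesterol biosynthesis genes did so too, among them FDFT1 at 117 ± 37.2 and HMGCS1 at 105 ± 33.2 RPKM. The glycolytic enzyme GAPDH stood at 1118 ± 257 RPKM. The chaperones HSPA8 and HSP90AA1 stood at 562 ± 170.3 and 527 ± 3.91 RPKM. Inducible HSPA1A and HSPA1B, near-identical copies whose reads can be split wrongly, were at 10.9 ± 3.82 and 19.8 ± 5.94 RPKM. Among p53 targets, CCNG1 was at 134 ± 6.88 RPKM, CDKN1A at 3.34 ± 1.51 and MDM2 at 3.77 ± 1.75 RPKM. Of the lysosome and autophagy genes, LAMP1 was highest at 32.6 ± 6.71 RPKM. Of the amino acid and ER stress genes, HSPA5 was highest at 188 ± 30.5 RPKM, and DDIT3 (CHOP) stood at 1.42 ± 0.618 RPKM. The adhesion and epithelial list, which also holds mesenchymal genes such as VIM (vimentin), was led by CLDN6 at 504 ± 135 RPKM. CDH1 (E-cadherin) stood at 68.4 ± 10.3 and VIM at 11.4 ± 8.85 RPKM. The WNT feedback targets were led by SP8 at 27.5 ± 5.38 RPKM, with AXIN2 at 6.05 ± 0.722 RPKM.

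The 2 libraries of the treated group were then compared with each other, since their spread sets what any comparison with these samples can resolve. Replicate 2 had the higher levels, in the median, of genes for glycolysis and the response to low oxygen, and replicate 1 had the higher levels, in the median, of the mesenchymal and the YAP target lists. BNIP3, a mitophagy receptor and hypoxia target, was 5.64-fold higher in replicate 2 (1078 against 6184 reads). SLC16A3, the lactate exporter MCT4, was 10.03-fold higher there, DDIT4, an mTORC1 inhibitor induced by stress and low oxygen, 8.52-fold, and MIR210HG, the host transcript of a hypoxia-induced microRNA, 10.4-fold. TAGLN was 10.8-fold higher in replicate 1 (4515 against 423 reads), the muscle filamin FLNC 11.6-fold and the collagen COL12A1 27.8-fold. The counting intervals of these 7 genes excluded equal levels. The 7 are among the largest differences, so that outcome followed from their choice and is no separate support. No replicate stands behind the difference of 2 single libraries.

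The log2 values of the 16148 tested genes correlated across genes with Pearson's r = 0.968 and Spearman's rho = 0.976; genes are not independent replicates. The biological coefficient of variation was 25.4%. A gap of at least 2-fold was seen for 1761 genes (10.9%), against 7.89% of the unchanged genes simulated with a coefficient of variation of 25%. Of the 1761 genes, 992 were higher in replicate 1 and 769 in replicate 2. With total reads as the scale in place of the authors' size factors, 601 of 1797 such genes were higher in replicate 2, and the median difference of all genes moved from 0.023 to -0.078 on the log2 scale. The counting interval excluded equal levels for 9387 genes (58.1%), and the chi-square statistic of the read counts was 51.8 per degree of freedom. Separately prepared libraries commonly exceed counting error, so these values show only that the 2 columns were not repeats of the same library, and each was counted as 1 replicate.

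**Figure D2:**
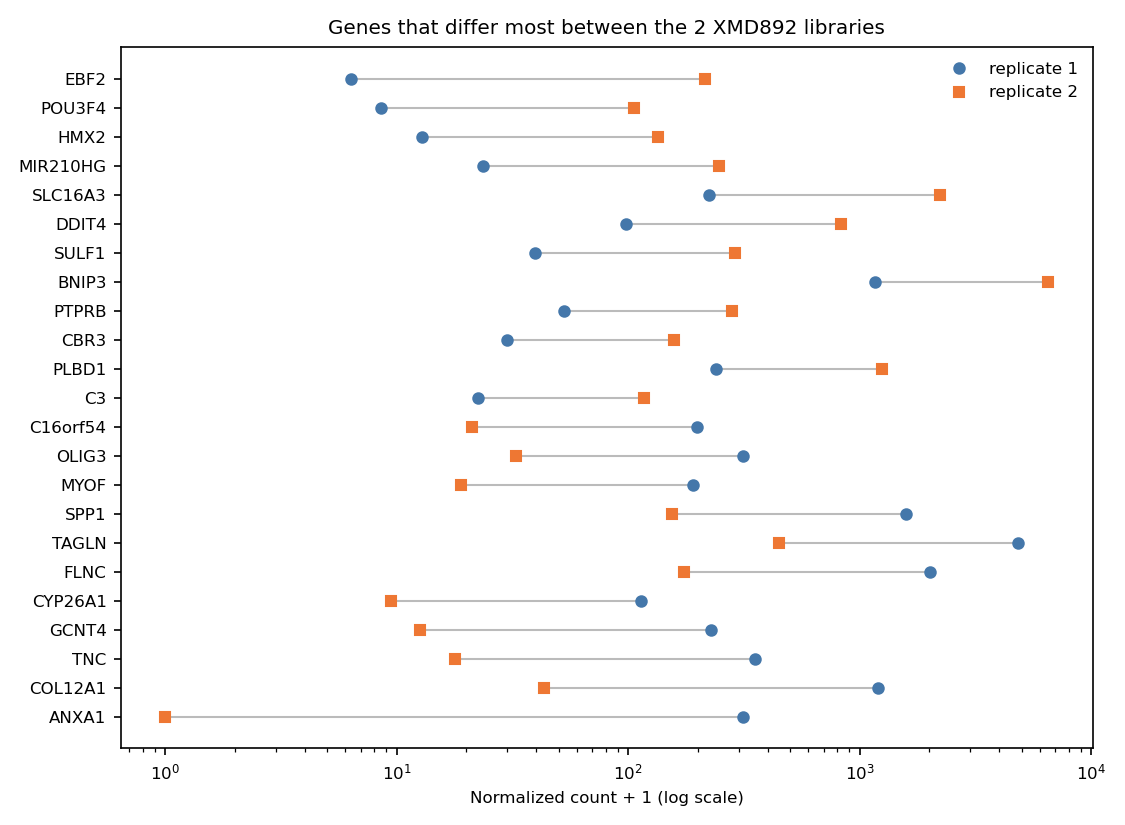
Normalized counts plus 1 (log scale) in replicate 1 (circles) and replicate 2 (squares) for genes among the 12 with the largest difference in each direction, of those with a mean normalized count of at least 50. TAGLN lies 10.8-fold higher in replicate 1 and SLC16A3 10.03-fold higher in replicate 2.

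Beyond the genes above, the 12 largest differences toward replicate 2 included EBF2 (33.8-fold, 5 against 203 reads), POU3F4 at 12.4-fold and HMX2 at 10.5-fold, which encode developmental transcription factors. The ratios of EBF2, POU3F4 and HMX2 rest on few reads in replicate 1. With a pseudocount of 5 the log2 difference was 4.40 in place of 5.08 for EBF2 and 3.13 in place of 3.63 for POU3F4. For HMX2 it was 3.04 in place of 3.39. The others were the heparan sulfate sulfatase SULF1 at 7.27-fold, the endothelial phosphatase PTPRB at 5.34-fold, the carbonyl reductase CBR3 at 5.28-fold, PLBD1 at 5.23-fold and complement C3 at 5.21-fold. Those toward replicate 1 included ANXA1 (annexin A1), which had 291 reads in replicate 1 and 0 in replicate 2. Against the limit of 3 reads that a count of 0 allows in 1 library, it was at least 98.7-fold higher in replicate 1. That limit leaves out the counting error of replicate 1's own reads, and the exact counting interval reached down to 79.7-fold. The matrix protein TNC was 19.7-fold higher in replicate 1, the glycosyltransferase GCNT4 18.04-fold and the retinoic acid hydroxylase CYP26A1 12.04-fold. SPP1 (osteopontin) was 10.3-fold higher, MYOF 10.1-fold, OLIG3 9.60-fold and C16orf54 9.38-fold. The ratios of GCNT4 (211 against 11 reads) and CYP26A1 (105 against 8 reads) rest on few reads in replicate 2. With a pseudocount of 5 the log2 difference was -3.80 in place of -4.17 for GCNT4 and -3.13 in place of -3.59 for CYP26A1. For each gene named here the counting interval excluded equal levels. Genes chosen for the largest gaps would do so by that choice, and 58.1% of all tested genes did, so this adds no support.

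Of 28 fixed lists with at least 5 tested members, 10 stood apart between the libraries, against 1.40 expected for lists of unrelated genes. The glycolysis and hypoxia list had 17 of 23 genes higher in replicate 2, and its median of 0.57 on the log2 scale lay above all 10000 random lists. With quantile normalization the median was 0.34, at percentile 99.9 of the random lists. PGK1 was 2.53-fold and LDHA 2.04-fold higher in replicate 2, while ADM was 2.14-fold higher in replicate 1. The G2/M list had 14 of 18 genes higher in replicate 2 with a median of 0.36, for example TOP2A at 1.58-fold and UBE2C at 1.56-fold, and a median of 0.22 after the correction for length and GC content. The cholesterol biosynthesis list had 19 of 23 higher there with a median of 0.26, for example HMGCS1 and FDFT1, both at 1.69-fold; with total reads as the scale its median was 0.16. The primitive streak and mesoderm list had 5 of 6 tested genes higher in replicate 2 with a median of 0.83, on low counts such as MIXL1 with 31 and 104 reads. Without the expression minimum it no longer stood apart, with a median of 0.35, and with a minimum of 50 too few members were left to test it.

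Toward replicate 1, the mesenchymal and fibroblast list had 6 of 10 tested genes higher and a median of -0.67, with COL1A1 7.39-fold higher in replicate 1 on 1429 and 196 reads and THY1 2.04-fold higher in replicate 2. The neuroectoderm list had a median of -0.54 with 7 of 10 genes higher in replicate 1, among them NES at 1.77-fold. The list of targets of YAP, a growth regulator that responds to cell density and tension, had a median of -0.44 with 10 of 12 genes higher in replicate 1. AXL was 3.32-fold and CYR61 1.89-fold higher there. Smaller shifts toward replicate 1 were seen for the p53 targets (16 of 22 genes, median -0.25), the G1/S and DNA replication genes (14 of 18, median -0.23) and the ribosome biogenesis genes (16 of 21, median -0.16, or -0.26 with total reads as the scale). The heat shock genes had 8 of 12 higher in replicate 1 and a median of -0.18, inside the central 95% of random lists; they stood apart with quantile normalization (median -0.27) and with the correction for length and GC content (-0.21). The mitochondrially encoded genes, which bear on RNA quality, did not stand apart, with 7 of 13 genes higher in replicate 2 and a median of 0.15. That direction turned with quantile normalization (median -0.21) and with a correction for length and GC content (-0.15, where the list stood apart).

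**Figure D3:**
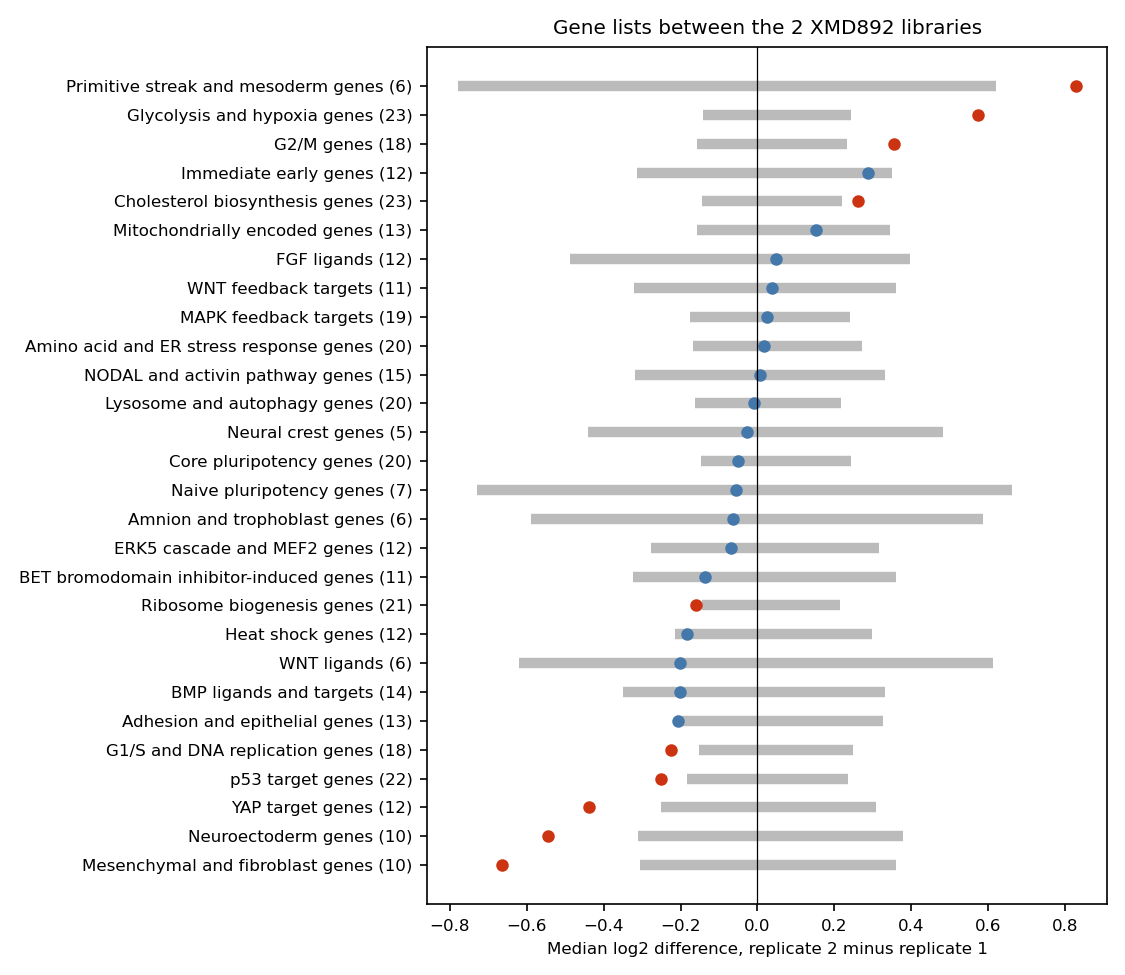
Median log2 difference, replicate 2 minus replicate 1, of each fixed gene list (points; red where the list stood apart) over the central 95% of 10000 random lists matched on expression (grey bars), with the number of tested genes in brackets. The glycolysis and hypoxia list lies at 0.57 and the mesenchymal and fibroblast list at -0.67.

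The genes closest to the study's question did not stand apart as groups on the authors' scale with the minimum of 10, and some did under an alternative. The core pluripotency list had a median of -0.051, although POU5F1 was 2.09-fold higher in replicate 2 and OTX2 3.75-fold higher in replicate 1. The NODAL and activin list had a median of 0.0069, with 8 of 15 tested genes higher in replicate 2. With a minimum mean normalized count of 50 it stood apart, with a median of 0.39. That median lay between SMAD7 at 0.17 and NODAL at 0.62, and it depended on single members. LEFTY2, at -0.93, fell just short of that minimum. With LEFTY2 kept, or with SMARCA2 left out, the middle value would be that of SMAD7. Whether the list would then stand apart was not tested, so a shift of the pathway is not shown. Among the list's members at least 2-fold higher in replicate 2 were SMARCA2 at 3.83-fold, LEFTY1 at 2.39-fold and GDF3 at 2.11-fold. NODAL was 1.53-fold higher in replicate 2 with a counting interval of 0.29 to 0.95 on the log2 scale. The MAPK feedback list had a median of 0.025, with DUSP6 2.20-fold and DUSP5 2.11-fold higher in replicate 2 and CCND1 1.45-fold higher in replicate 1. With total reads as the scale the NODAL and MAPK feedback medians turned to -0.094 and -0.076. The immediate early genes had 10 of 12 tested genes higher in replicate 2 and a median of 0.29, inside the central 95% of random lists; after the correction for length and GC content the list stood apart, with a median of 0.38. The ERK5 cascade and MEF2 list had a median of -0.069, and MAPK7 was 1.21-fold higher in replicate 1 with a counting interval of -0.45 to -0.11. The counting intervals of FGF8, WNT3, TGFB1, BMP4 and MAP2K5 included equal levels, so no difference between the libraries was detectable for these genes at this depth.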

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

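The comparison with E8 was not run, and neither were the alternatives planned for it: limma without a trend, edgeR or DESeq2 tests, the 1.5-fold threshold, camera with an estimated correlation and fry. No paired analysis was possible because no untreated library was matched to a column, so there was no second group to share replicate numbers with. Leaving out a library leaves no difference between libraries to compute; the number of genes at 1 RPKM was 11942 without replicate 1 and 12263 without replicate 2. The number of genes with a gap of at least 2-fold depended on the expression minimum, at 3350 with no minimum and 711 with a mean normalized count of at least 50, against 1761; the number of genes tested differs between these settings by construction. It stayed between 1401 and 1808 under the other alternatives, of which the total-read scale and the length and GC correction were added after the data were seen, as were the RPKM alternatives. The thresholds of 0.5 and 2 RPKM gave 13186 and 9522 genes, and the longest transcript's length gave 12034. The biological coefficient of variation ranged from 23.2% to 26.01%, and Pearson's r from 0.962 to 0.973. The number of gene lists standing apart ranged from 9 to 13. The lists that stood apart kept the direction of their median in every alternative in which they could be tested; the primitive streak and mesoderm list had too few members left to test at the minimum of 50, and without a minimum it no longer stood apart. Among lists that did not stand apart, the naive pluripotency, NODAL, FGF ligand, MAPK feedback, WNT feedback, neural crest and amino acid stress lists had medians near 0 that changed sign under at least 1 alternative. The mitochondrially encoded genes, which did not stand apart, moved from a median of 0.15 to -0.15 with the length and GC correction and stood apart there; the cause was not tested beyond that correction. Depth limits the ligand genes: FGF8, FGF4 and WNT3 rest on under 100 reads per library.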

Other observations

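Receptors for proteins in the medium, and receptors for other ligands, were expressed in the treated cells. FGFR1 stood at 34.8 ± 1.84 RPKM (SD, n = 2), FGFR4 at 14.6 ± 0.391, FGFR2 at 10.8 ± 1.90 and FGFR3 at 10.6 ± 5.12 RPKM. The activin and TGFβ receptors TGFBR1, ACVR1B and ACVR2B stood at 14.1 ± 1.13, 8.61 ± 0.566 and 7.67 ± 2.14 RPKM, and TGFBR2 at 2.84 ± 0.399 RPKM. The BMP receptors BMPR1A and BMPR2 stood at 10.8 ± 0.191 and 3.18 ± 0.125 RPKM. ERBB2 was at 34.5 ± 15.6, IGF1R at 9.42 ± 3.51 and INSR at 2.15 ± 0.230 RPKM. Of the 24 receptors in this list, 19 reached 1 RPKM in both libraries. On the scale of the authors' normalized counts, 0 differed 2-fold between the libraries. RPKM is scaled by total reads, so ratios of RPKM, such as that of FGFR3, can differ from these.

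Among long intergenic RNAs, LINC00678 reached 161 ± 28.6 RPKM and LNCPRESS2 reached 56.9 ± 12.3 RPKM. Of 20 imprinted genes, 16 were listed and 10 reached 1 RPKM in both libraries. NNAT stood at 99.7 ± 31.4 RPKM, PEG10 at 61.4 ± 19.6 and MEST at 39.99 ± 3.92 RPKM. H19 stood at 1.40 ± 0.124 RPKM and PEG3 at 0.0631 ± 0.0749 RPKM, on 21 and 2 reads. SNRPN and SNURF overlap, and their reads cannot be assigned with certainty.

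In the paragraphs that follow, the length and GC correction, the random lists matched on transcript length, and the tests of the second HIF list, the actin list, the second fibroblast list and the ribosomal protein genes were chosen after the differences between the libraries had been seen. The labels give no group that parts the 2 libraries, so no biological explanation from the design was tested. The second HIF list, the actin list and the second fibroblast list hold no gene of the fixed list whose pattern they test. Related genes had already been seen among the largest differences, such as BNIP3 and SLC16A3 for the HIF list and TAGLN and FLNC for the actin list. Genes that vary together would lean the same way. The place of these 2 lists among random lists of unrelated genes is therefore little separate support.

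The glycolysis and hypoxia genes were higher in replicate 2, and a bias from transcript length and GC content is argued against as the whole cause: with both corrected, the list's median was 0.58 against 0.57 before, still above all random lists, and 0.34 with quantile normalization alone. A second list of 25 HIF targets had 21 genes higher in replicate 2 and a median of 0.66, above all 10000 random lists, with BNIP3L, MXI1, CCNG2 and P4HA2 at 2.92-fold, 2.94-fold, 3.06-fold and 2.74-fold. As a hypothesis, the cells of replicate 2 may have had less oxygen, for example in a denser culture. ADM went the other way, and a difference of day or handling that the labels do not record stays open.

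The YAP target list had 10 of 12 genes higher in replicate 1; the mesenchymal list was divided, with 6 of 10 genes higher there and its most abundant member, THY1, 2.04-fold higher in replicate 2, although its median also leaned toward replicate 1. After the length and GC correction the YAP target list still had a median of -0.33 and the mesenchymal list one of -0.64, both below the 2.5th percentile of random lists, which argues against that bias as the whole cause. A list of 20 actin and SRF targets had 14 genes higher in replicate 1 and a median of -0.60, below all random lists, with TPM1 at 3.26-fold, CSRP1 at 2.52-fold and CNN1 at 2.54-fold; as a hypothesis, this is consistent with stronger actin-linked transcription in replicate 1. Of the fixed mesenchymal and fibroblast list, COL3A1, DCN, LUM, POSTN and TWIST1 were not listed. The rule by which genes entered the table is not given, so their absence was not read as 0. Fibroblast-like cells in replicate 1 stay open, since a second list of fibroblast genes went both ways. Of its 21 genes 10 were higher in replicate 2, with a median of -0.0066. After the length and GC correction 12 of 21 were higher there, with a median of 0.040. With total reads as the scale the median was -0.11. Of those 21 genes 14 reached 1 RPKM in both libraries, the most abundant being FSTL1 at 59.6 ± 3.15, SFRP1 at 56.6 ± 20.9 and COL6A1 at 54.00 ± 7.06 RPKM, and the fixed BMP list also holds GREM1.

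Cytoplasmic ribosomal protein genes were higher in replicate 2, 79 of 84 of them, with a median of 0.65, or 0.41 with quantile normalization. Shorter transcripts tended to be higher in replicate 2, with Spearman's rho = -0.16 between the difference and transcript length across 15793 genes, which are not independent. Random lists matched on both expression and transcript length had medians centred on 0.22, with 95% of them between 0.14 and 0.31. Length bias is thus argued against as the whole cause, as far as annotated transcript length measures it. The lengths of the transcripts actually expressed were not known. Other differences in RNA handling or library preparation were not tested.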
